A study of Mus musculus with 6 samples.

How the data were processed

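Liver total RNA of Swiss-Webster mice was hybridized to 6 Affymetrix expression arrays, 2 for each of control diet, fraction 1 (hexane) and fraction 2 (methanol). The groups were taken from the titles of the samples. The deposited table holds 1 signal intensity per probe set and array, as a linear value. The software and the summary method that made it are not given in the sources used here, and it holds no detection calls. Its values were used as deposited, because the mean of each array without the lowest and highest 2% of probe sets was equal over the arrays within 0.082%, as the authors' scaling would leave it. The authors' experiment files gave the scan batch and the chip lot of each array and no measurement: there were 2 scan batches and 3 chip lots. The number of arrays limits the precision.

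Of 22690 probe sets, 64 control probe sets were left out. Gene symbols came from the platform annotation and were checked against a gene table through the Entrez ID: 20393 probe sets had 1 symbol, 691 had several and 1606 had none. Of those with 1 symbol, 20364 matched the table and 0 symbols changed. No gene was named from a probe set with several symbols. A probe set was tested if at least 2 of the 6 arrays were at or above that array's 40th percentile, which left 14755. For values per gene, the probe set with the highest mean log2 value among tested probe sets with 1 symbol stood for the gene, which gave 9209 genes. No genome build was given, so no coordinates are printed.

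Values were taken as log2 of signal plus 16. The 3 comparisons were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a variance trend) over all 6 arrays, with 3 residual and 5.43 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Where under 10 probe sets passed, the count at an unadjusted p under 0.01 with at least a 2-fold change was given as well. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 against the other genes, adjusted over the 44 lists with at least 4 tested members out of 46 fixed lists. Camera with an estimated correlation and fry, which asks whether a list's genes move in a common direction without comparing them with other genes, were run beside it. Counts adjusted over the list alone adjust the same limma p-values over the members of 1 list. The groups, the tests, the filter, the lists of genes, the rule for named genes and the alternatives were fixed before the data were examined. The fit to the 4 arrays of scan batch 1 alone and the fit with chip lot as a block were added afterwards.

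Genes were named by a rule. For each comparison it took the 8 largest increases and the 8 largest decreases among genes past the threshold whose groups did not overlap. Where fewer than 8 passed, the places left went to genes with the smallest p among those with non-overlapping groups and at least a 2-fold change, given as values. It also took up to 4 members of each list with the smallest p, of which the text gives a selection. Among genes fixed in advance, it took Cyp7a1, Cyp3a11, Cyp2b10, Cyp1a2, Cyp4a14, Abcb1a, Fasn, Alox5 and Saa1 in every comparison if tested; Alox5 was not. Clones and loci known only by a number were skipped.

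The procedure was tested on simulated data of the same size and spread, with 100 probe sets changed by each fold in 10 draws. Of probe sets changed 2-fold it recovered 37.9% for fraction 1 against control, 41.9% for fraction 2 against control and 36.1% between the fractions, and of those changed 4-fold 87.8%, 87.6% and 87.0%. The share of false calls was 8.78%, 8.16% and 8.68%, above the nominal 5%. Of 200 planted lists of 20 genes shifted by 0.5, camera recovered 100% with the preset correlation in each comparison, and called 1%, 0.5% and 3% of unshifted ones. With an estimated correlation it recovered 99.5%, 97% and 95.5%. The genes of these simulated lists varied independently, which real lists need not do.

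To set the correlation of the fold changes beside what shared controls give, unchanged groups were simulated 100 times against the same control arrays, and again in each design with an array left out, with scan batch 1 alone or with a block. The alternatives changed 1 choice at a time: quantile normalization, centring each array on its median, pseudocounts of 1 and 64, a floor of 50, no filter, a filter at the 60th percentile, no variance trend, scan batch as a block, a fit to the groups compared alone, a plain test per probe set without moderation, leaving out each array in turn, other probe sets of the same gene, and the replicate letters as a block between the fractions. Without 1 array, its group has a single array that is assumed to vary like the other groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.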

Results

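Liver RNA of Swiss-Webster mice was measured on 6 Affymetrix expression arrays. Boswellia serrata is the tree whose gum resin is known as Indian frankincense. Of the arrays, 2 came from mice on a control diet, 2 from mice given fraction 1, extracted with hexane, and 2 from mice given fraction 2, extracted with methanol. Each fraction made up 1% of the diet for 21 days. The table held 22690 probe sets, of which 14755 were bright enough to be tested and stood for 9209 genes. Median signals were similar, from 139 to 167 array units. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.25. Nothing in the labels says whether the replicates were separate animals or pools, so the p-values measure only the spread between these samples. The 3'/5' signal ratio of the actin control probe sets, a sign of RNA quality, was 3.87 in control replicate 2 and 2.13 to 2.64 in the other 5 arrays. For Gapdh it was 1.74 in control replicate 2 and 1.07 to 1.38 elsewhere. The arrays were scanned in 2 batches: control replicate 1 and fraction 2 replicate a in batch 2, the other 4 arrays in batch 1. Batch 2 held no fraction 1 array, so a within-batch value for fraction 1 comes from batch 1 alone. Against control, that value rests on control replicate 2 as the only control, and equals the change without control replicate 1. Against fraction 2, it rests on fraction 2 replicate b alone. A within-batch value of fraction 2 against control sets a single array against a single array. Chip lot 1 held control replicate 2 and fraction 1 replicate a, lot 2 the 2 arrays of batch 2, and lot 3 fraction 1 replicate b and fraction 2 replicate b. The differences control replicate 1 minus 2 and fraction 2 replicate a minus b, which both set batch 2 against batch 1, had r = 0.296 across probe sets. The control arrays correlated less with each other (r = 0.941) than the arrays of fraction 1 (0.970) or fraction 2 (0.969). Control replicate 1 was closer to fraction 2 replicate a (0.971), fraction 2 replicate b (0.962) and fraction 1 replicate a (0.949) than to control replicate 2. With fraction 1 replicate b it had r = 0.937. The fit with chip lot as a block was chosen after the results were seen and leaves 1 residual degree of freedom.

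The comparison of fraction 1 with control asked which liver genes differed after the hexane fraction was fed. Cyp2c55 and Cyp2b10, cytochromes P450 of drug metabolism, and the glutathione S-transferases Gstm2 and Gstm3 rose. Of 14 genes known to be expressed more strongly in male than in female mouse liver, 8 fell (adjusted p = 2.99e-16 for the list with camera; adjusted p = 0.314 with an estimated correlation). Cyp2c55, inducible by foreign compounds, went from 243 ± 36.4 to 8969 ± 703 array units (mean ± SD, n = 2). Hsd3b5, a steroid-metabolizing enzyme of male mouse liver, went from 5220 ± 756 to 8.25 ± 0.071 array units (n = 2). With camera at the preset correlation, genes of cholesterol synthesis and proteasome subunits were shifted up as groups, and coagulation and complement genes and interferon-stimulated genes down. With an estimated correlation these 4 lists did not pass (adjusted p = 0.509, 0.336, 0.4 and 0.314).

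After fraction 1, 105 of 14755 probe sets passed an adjusted p of 0.05 with limma, 54 of them higher and 51 lower. They stood for 85 genes, 42 higher and 43 lower, while 10 probe sets had no single gene symbol. In each of the 105, both fraction 1 arrays lay beyond both control arrays. Over all probe sets, 6033 showed such a separation, or 40.9% where chance gives 33.3%. At an unadjusted p under 0.05 there were 1829 probe sets, against 738 by chance. With scan batch as a block 118 passed, 70 higher and 48 lower, and 77 were called in both fits. With chip lot as a block 100 passed, 68 of them among the 105.

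**Figure D1:**
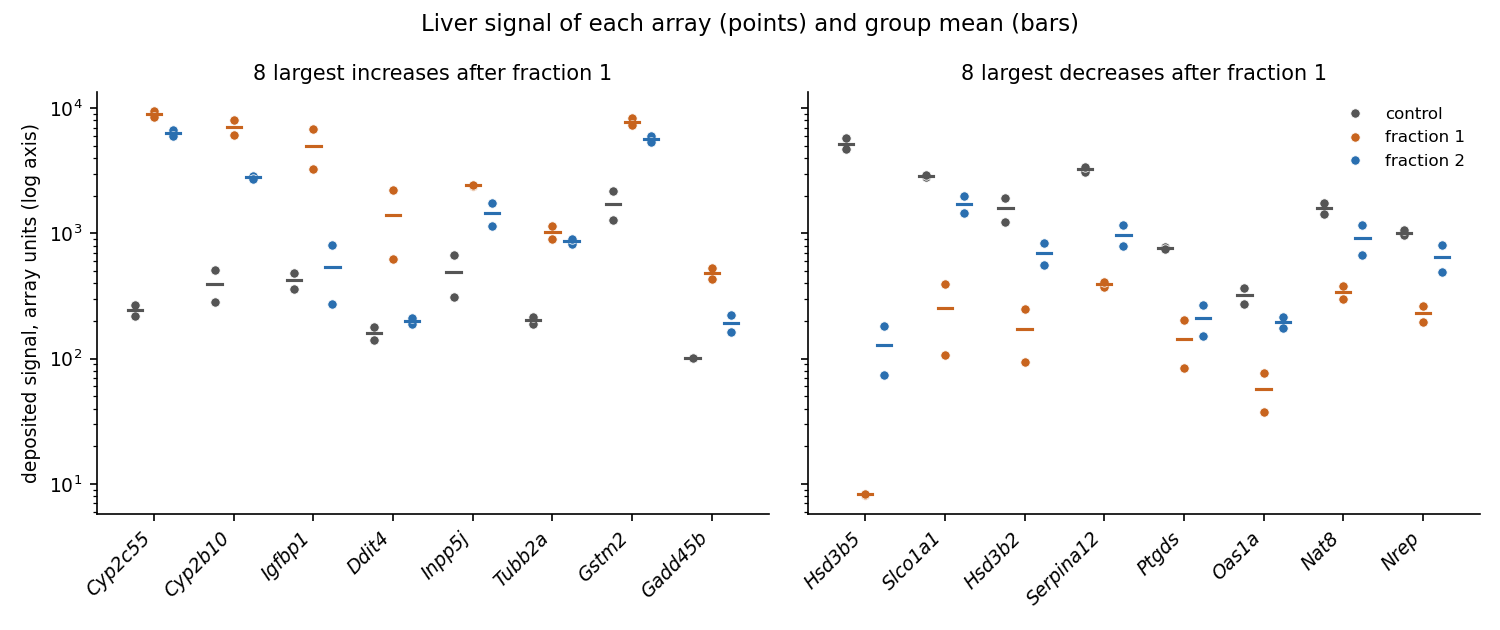
Deposited signal in array units (log axis) of 8 genes that rose and 8 that fell after fraction 1. Among the named genes that passed in that comparison, they had the largest increases and decreases. Points are the 2 arrays of each group and bars are group means. Cyp2c55 lay at 8969 after fraction 1 and 6342 after fraction 2 against 243 in control, and Hsd3b5 at 8.25 and 128 against 5220.

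Among the named genes that passed, the largest increases after fraction 1 were those of Cyp2c55 (log2 fold change 5.12 ± 0.17 SE, adjusted p = 1.14e-05) and Cyp2b10 (4.15 ± 0.27, adjusted p = 5.54e-04). Cyp2b10 is the classical target of the nuclear receptor CAR. With scan batch as a block their changes were 5.08 and 3.97, and within batch 1 they were 4.98 and 3.74. Igfbp1, which binds insulin-like growth factors, rose by 3.45 ± 0.49 (adjusted p = 0.0301). Ddit4, an inhibitor of mTOR signalling, rose by 2.77, a call that held in only 3 of 19 alternatives. Among others, it was lost with scan batch as a block (adjusted p = 0.0789), with chip lot as a block (adjusted p = 0.0682) and after quantile normalization. Inpp5j, Tubb2a and Gstm2 rose by 2.36, 2.24 and 2.21. Gadd45b, a stress-response gene, rose by 2.08, although a dimmer probe set of the same gene stood at -0.14. The probe sets of Cyp2b10, Tubb2a and Gadd45b belong to a type that can match several related transcripts. The largest decrease was that of Hsd3b5 at -7.75 ± 0.35 (adjusted p = 6.58e-05). Its signal after fraction 1 lay below the pseudocount of 16, so the fold depends on that constant and ran from -9.13 to -6.18 over the alternatives. Slco1a1, an uptake transporter of organic anions, fell by 3.67, and Hsd3b2 and Serpina12 changed by -3.19 and -3.00. Decreases of Ptgds, Oas1a, Nat8 and Nrep ran from -2.41 to -2.08.

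Of 14 measured male-biased liver genes, 8 fell and 6 did not pass. Adjusted over the list alone, 11 fell, and 13 of the 14 lay below 0. The list's median was -1.54 (adjusted p = 2.99e-16 with camera; adjusted p = 0.314 with an estimated correlation). It was -1.47 with scan batch as a block (adjusted p = 2.32e-12) and -1.58 within batch 1. Examples are Hsd3b5, Slco1a1, Serpina12 and Cyp7b1, an oxysterol hydroxylase that fell by 1.55. The call of Cyp7b1 held in 9 of 19 alternatives. Of these 14 genes 7 also stand in other lists, among them the complement genes C6 and C8b. No female-biased gene of 9 passed, also when adjusted over the list alone, and their median was 0.44 (adjusted p = 0.147); it was 0.07 with scan batch as a block (adjusted p = 0.358), 0.17 within batch 1 and 0.17 with chip lot as a block. The sex of the mice is not in the labels. The Y-linked Eif2s3y stood at 0.07 and was at -0.45 without control replicate 2. Xist, expressed from the inactive X chromosome of females, stood at 0.47 (adjusted p = 0.677) and at 0.04 with scan batch as a block; it read 131.8 and 262.7 array units in control and 261.8 and 267.5 after fraction 1. A dimmer Xist probe set, too dim to be tested, read 5.3 and 26.3 against 56 and 30.6. Another, dimmer still, read 2.8 and 5.8 against 4.6 and 3.1.

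Of 18 target enzymes of the receptors CAR and PXR, 4 rose and 14 did not pass; adjusted over the list alone, 8 rose. The median was 0.42, and 17 members lay above 0 (adjusted p = 4.99e-11 with camera; adjusted p = 0.314 with an estimated correlation). The blocked median was 0.29 (adjusted p = 1.89e-08), and that within batch 1 was 0.28; without fraction 1 replicate b it was 0.64. Besides Cyp2c55 and Cyp2b10, the carboxylesterase Ces2a rose by 1.07 and Aldh1a7 by 0.78, the latter call lost with scan batch (adjusted p = 0.0574) or chip lot (adjusted p = 0.0665) as a block and whichever array was left out, while Cyp3a11, a known PXR target, stood at 0.16 (adjusted p = 0.734). Of 22 target genes of Nrf2, a regulator of antioxidant defence, 5 rose and 17 did not pass; adjusted over the list alone, 12 rose. Their median was 0.64 (adjusted p = 6.86e-12 with camera; adjusted p = 0.4 with an estimated correlation), 0.75 in the blocked fit (adjusted p = 8.87e-14) and 0.78 within batch 1. The glutathione S-transferases Gstm2, Gstm3, Gstm4 and Gsta2 rose by 0.96 to 2.21, and a dimmer probe set of Gstm3 by 3.80. The call of Gsta2 was lost whichever array was left out. Of 23 phase II conjugation genes, 2 rose (Gstt3 by 1.62, Ugdh by 1.40), Ugt2b38 fell and 20 did not pass; the call of Ugt2b38 was lost with scan batch (adjusted p = 0.0593) or chip lot (adjusted p = 0.102) as a block and whichever array was left out. Adjusted over the list alone, 7 rose and 5 fell. That list's median was -0.13 and its mean 0.01 (adjusted p = 0.929). Of 16 hepatic transporters, Slco1a4 rose by 2.07 and Slco1a1 fell, and adjusted over the list alone 4 rose and 4 fell (median -0.18, adjusted p = 0.8).

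Of 19 genes of cholesterol synthesis, Hmgcs1 (1.07) and Sqle (1.31) rose and 17 did not pass. Adjusted over the list alone, 8 rose and 2 fell. The median was 0.60 (adjusted p = 2.08e-06 with camera; adjusted p = 0.509 with an estimated correlation). It was 0.63 in the blocked fit (adjusted p = 8.10e-09) and 0.61 within batch 1. In bile acid synthesis, with 16 genes, the oxysterol hydroxylase Cyp39a1 rose by 1.93, Cyp7b1 fell and 14 did not pass; adjusted over the list alone, 4 rose and 3 fell. The call of Cyp39a1 was lost with scan batch as a block (adjusted p = 0.0562). That list's median was -0.18 (adjusted p = 0.444), and Cyp7a1, the rate-limiting enzyme, stood at 1.06 (adjusted p = 0.277). None of 33 PPAR-alpha target and fatty acid oxidation genes passed, and adjusted over the list alone 2 rose and 3 fell (median -0.19, adjusted p = 0.0936). Cyp4a14, Cyp1a2, Fasn, Abcb1a and Saa1, fixed in advance as readouts, stood at -1.14, -0.48, 0.04, 0.74 and -0.38, with adjusted p from 0.19 to 0.977. Cyp4a14 and Saa1 turned to 0.05 and 0.73 without fraction 1 replicate b. Cyp3a11 turned to -0.05 without control replicate 1, and Fasn to -0.44 and -0.03 without control replicate 2 and fraction 1 replicate a.

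Of 37 proteasome subunits none passed over all genes, while adjusted over the list alone 5 rose and 1 fell. Their median was 0.31, with 31 above 0 (adjusted p = 4.53e-07 with camera; adjusted p = 0.336 with an estimated correlation). It was 0.37 in the blocked fit (adjusted p = 8.27e-10) and 0.33 within batch 1. Psmd14 stood at 0.79, whereas the immunoproteasome subunit Psmb10 stood at -0.74. Of 20 interferon-stimulated genes, Oas1a fell by 2.25, a call that held in 9 of 19 alternatives, and the rest did not pass. Adjusted over the list alone, 7 of the 20 fell. The median was -0.58 (adjusted p = 1.77e-06 with camera; adjusted p = 0.314 with an estimated correlation), -0.58 in the blocked fit (adjusted p = 2.33e-06) and -0.59 within batch 1. Of 26 coagulation and complement genes, C6 (-1.79), C8b (-1.51) and C9 (-1.73), all parts of the membrane attack complex, fell and 23 did not pass. The calls of C6, C8b and C9 held in 9, 14 and 10 of 19 alternatives. Adjusted over the list alone, 11 fell. The median was -0.36, with 25 below 0 (adjusted p = 1.35e-09 with camera; adjusted p = 0.4 with an estimated correlation). It was -0.36 in the blocked fit (adjusted p = 3.10e-08) and -0.41 within batch 1. In the acute phase list, with 27 genes, Mt1 rose by 1.96 and 26 did not pass; adjusted over the list alone, 6 rose and 1 fell. That list's median was -0.08 while its mean was 0.26 and its test direction up (adjusted p = 0.444).

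Of 8 hepatocyte markers none passed, also when adjusted over the list alone; their median was -0.27 (adjusted p = 0.00483 with camera; adjusted p = 0.6 with an estimated correlation). It was -0.13 without control replicate 2 (adjusted p = 0.064), -0.18 without fraction 1 replicate b (adjusted p = 0.0756) and -0.07 after quantile normalization (adjusted p = 0.323). The blocked median was -0.29 (adjusted p = 0.0241), and that within batch 1 was -0.36. Over the alternatives, adjusted p ran from 4.04e-04 to 0.323. No Kupffer cell or macrophage marker of 17 passed, also when adjusted over the list alone (median -0.19, adjusted p = 0.39).

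Of 44 tested lists 16 passed with the preset correlation, 5 up and 11 down, and 0 with an estimated one. The calls of 7 of the 16 held in every alternative of scaling, filter, fit and left-out array that kept the preset correlation: male-biased, CAR and PXR, Nrf2, cholesterol synthesis, interferon, coagulation and complement, and proteasome. Their highest adjusted p over the alternatives were 2.63e-09, 4.06e-06, 1.58e-06, 0.0354, 2.35e-04, 2.91e-06 and 0.00126. The count of 105 became 149 without control replicate 1, 55 without control replicate 2, 47 and 14 without fraction 1 replicate a and b, and 38 without either fraction 2 array. Of 34 genes named here that passed, these same omissions ended the calls of 7, 21, 18, 26, 15 and 15, and of the 16 lists they ended 6, 5, 1, 4, 1 and 1. Whichever array was left out, Cyp2c55, Cyp2b10, Gstm3 and Slco1a4 rose and Hsd3b5 and Serpina12 fell. Ddit4, Ptgds, Hmgcs1, Sqle, Cyp39a1, Ugdh and Mt1 each kept the call in only 1 of the 6 omissions.

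**Figure D2:**
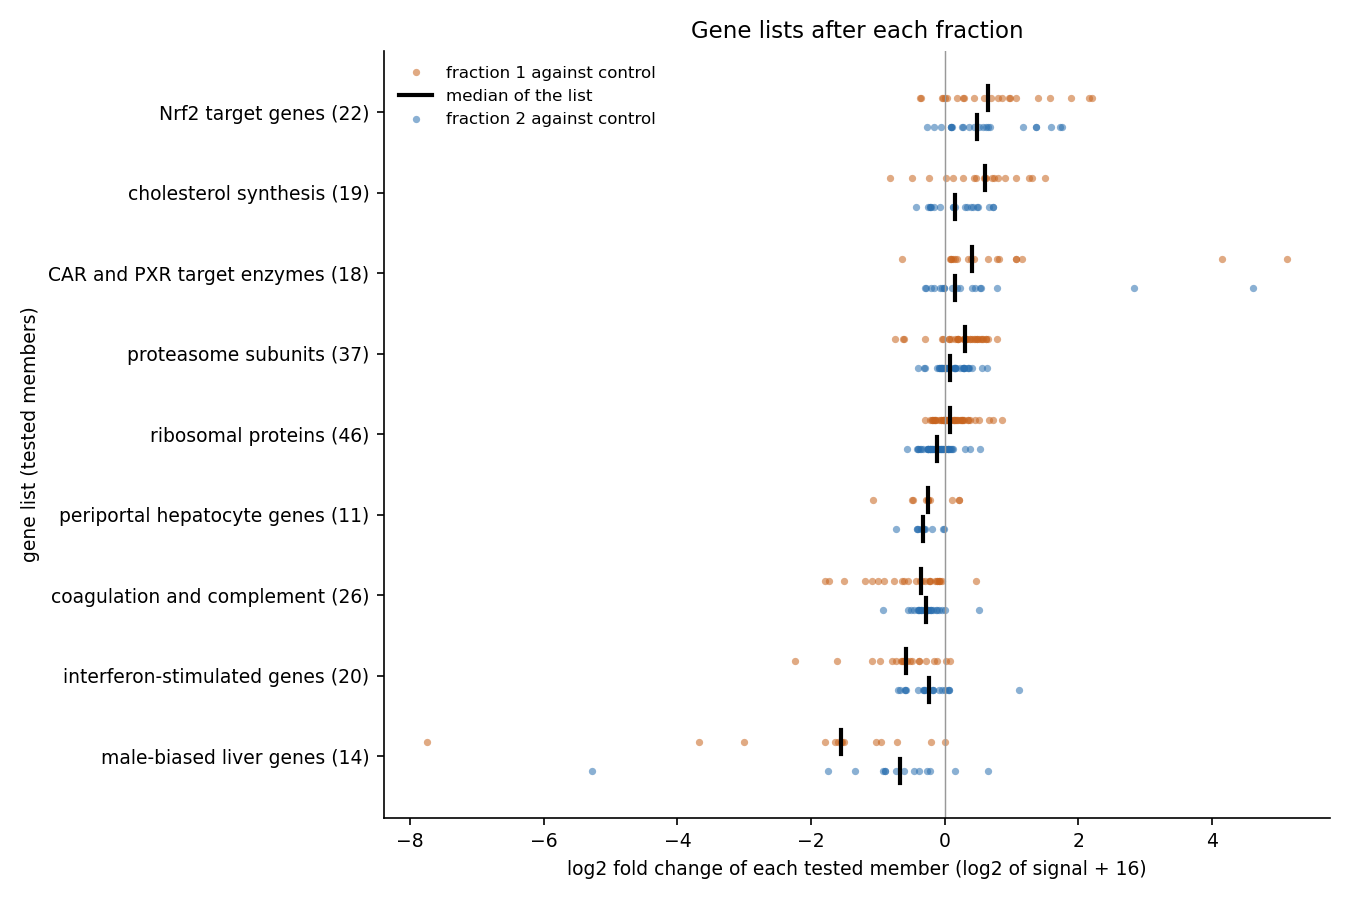
Log2 fold change against control of each tested member (points) and the median (black bars) of 9 gene lists, after fraction 1 and after fraction 2, with the number of members in brackets. Shown are the lists whose call held in every alternative of scaling, filter, fit and left-out array in some comparison. Male-biased genes had medians of -1.54 and -0.67, and Nrf2 targets 0.64 and 0.48.

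The comparison of fraction 2 with control asked the same of the methanol fraction. Cyp2c55, Cyp2b10, Gstm2 and Gstm3 again rose, and Hsd3b5 again fell. Cyp2c55 reached 6342 ± 428 array units against 243 ± 36.4 in control, and Cyp2b10 2799 ± 122 against 396 ± 160 (mean ± SD, n = 2). Hsd3b5 was at 128 ± 76.2 against 5220 ± 756 array units (n = 2). With camera at the preset correlation, Nrf2 targets were shifted up as a group, and male-biased genes, coagulation and complement genes and periportal hepatocyte genes down. With an estimated correlation these 4 lists did not pass (adjusted p = 0.418, 0.418, 0.52 and 0.418). The general hepatocyte markers had a median of -0.40, against -0.27 for coagulation and complement genes and -0.33 for periportal genes.

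After fraction 2, 16 of 14755 probe sets passed with limma, 14 higher and 2 lower. They stood for 11 genes, 9 higher and 2 lower, and 3 had no single symbol. In all 16 both fraction 2 arrays lay beyond both controls, as they did for 5188 probe sets in all, or 35.2% where chance gives 33.3%. At an unadjusted p under 0.05 there were 1026, against 738 by chance. The blocked fit called 24, 20 higher and 4 lower, 15 of them called in both fits. Control and fraction 2 were each split evenly over the scan batches, so the block cannot alter their fold changes, only the spread and p-values. Blocked medians after fraction 2 therefore repeat the unblocked ones and are no test of a batch effect on their size. With chip lot as a block 10 passed, 7 higher and 3 lower, 8 of them among the 16, and Btbd2, Tubb2a, Gstm2, Slco1a4, Abcc3 and Serpina12 lost their calls (adjusted p from 0.0509 to 0.0864).

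Cyp2c55 rose by 4.62 ± 0.17 (adjusted p = 2.69e-05), by 4.41 within batch 1 and by 4.84 within batch 2. Cyp2b10 rose by 2.83 ± 0.27 (adjusted p = 0.00918), by 2.38 and 3.28 within the batches. Btbd2 and Cyp2g1, a cytochrome P450 best known from the olfactory mucosa, rose by 2.20 and 2.06, and Tubb2a by 2.01. Hsd3b5 fell by 5.28 ± 0.35 (adjusted p = 0.00119), with -6.00 within batch 1 and -4.57 within batch 2. Serpina12, the other gene that fell, changed by -1.75 (adjusted p = 0.0385), a call lost whichever array was left out, with median centring and with no filter. Where places were left, genes with the smallest p were taken, and their values did not pass: Ttc39c at -1.06 (adjusted p = 0.0568), Mast3 at -1.18, and Rtp4, Ptgds, Atp4b and Ugt2b38 from -1.84 to -1.05.

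Of 22 Nrf2 targets, Gstm2 (1.76), Gstm3 (1.72) and the export pump Abcc3 (1.37) rose and 19 did not pass, the call of Abcc3 being lost whichever array was left out; adjusted over the list alone, 11 rose. The median was 0.48, with 19 above 0 (adjusted p = 9.57e-13 with camera; adjusted p = 0.418 with an estimated correlation). The blocked median was 0.48 (adjusted p = 3.57e-12), and the medians within batches 1 and 2 were 0.51 and 0.46. Of 18 CAR and PXR targets, Cyp2c55 and Cyp2b10 rose and 16 did not pass; adjusted over the list alone, 4 rose. The median was 0.15, with 10 above 0 (adjusted p = 9.44e-05 with camera; adjusted p = 0.418 with an estimated correlation). In the blocked fit it was 0.15 (adjusted p = 4.38e-04), and within the batches 0.18 and 0.19. It was 0.23 without fraction 2 replicate a and 0.26 with each array centred on its median. Among 16 hepatic transporters, Slco1a4 (1.59) and Abcc3 rose, and adjusted over the list alone 2 rose and 2 fell (median -0.05, mean 0.07, adjusted p = 0.321).

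Of 14 male-biased genes, Hsd3b5 and Serpina12 fell and 12 did not pass, while adjusted over the list alone 7 fell. The median was -0.67 (adjusted p = 5.22e-09 with camera; adjusted p = 0.418 with an estimated correlation), and -0.67 in the blocked fit (adjusted p = 1.34e-07). Within batches 1 and 2 it was -0.83 and -0.48, and with chip lot as a block -0.32. None of 26 coagulation and complement genes passed, and adjusted over the list alone 1 fell. Their median was -0.27, with 24 below 0 (adjusted p = 1.71e-05 with camera; adjusted p = 0.52 with an estimated correlation). It was -0.27 in the blocked fit (adjusted p = 4.01e-05), -0.39 and -0.19 within the batches, and -0.18 without control replicate 2 and with chip lot as a block. After quantile normalization and median centring it was -0.18 and -0.16. None of 11 periportal hepatocyte genes passed, and adjusted over the list alone 2 fell. All 11 lay below 0, with a median of -0.33 (adjusted p = 1.33e-04 with camera; adjusted p = 0.418 with an estimated correlation). It was -0.33 in the blocked fit (adjusted p = 6.76e-04), and -0.39 and -0.30 within the batches. After quantile normalization and median centring it was -0.10 and -0.21. The brightest 2% of probe sets, without the hepatocyte markers, also had a median of -0.21 after fraction 2. Whether the periportal and the coagulation and complement shifts go beyond a general shift of bright probe sets was not tested.

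None of 8 hepatocyte markers passed over all genes, and adjusted over the list alone 7 fell, with Alb at -0.42 and Ttr at -0.47. Their median was -0.40 (adjusted p = 2.42e-06 with camera; adjusted p = 0.52 with an estimated correlation), and -0.40 in the blocked fit (adjusted p = 4.60e-05). Within batches 1 and 2 it was -0.54 and -0.29, and after quantile normalization it was -0.03 (adjusted p = 0.953, the highest over the alternatives; the lowest was 4.00e-07). Interferon-stimulated genes had a median of -0.24 and did not pass (adjusted p = 0.0566). Of the genes fixed in advance, Cyp7a1, Cyp4a14, Abcb1a, Fasn and Saa1 stood at 0.37, -1.09, 0.64, 0.19 and 1.38, with adjusted p from 0.607 to 0.884. Cyp3a11 and Cyp1a2 both stood at -0.01. Without control replicate 2, Cyp7a1 turned to -0.30, Fasn to -0.28 and Cyp3a11 to 0.20, and Cyp1a2 turned to 0.29 without control replicate 1 and to 0.22 without fraction 2 replicate b. With chip lot as a block Cyp3a11 and Cyp1a2 turned to 0.10 and 0.06.

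Of 44 lists 17 passed with the preset correlation, 7 up and 10 down, and 0 with an estimated one. Of the 17, 5 held in every alternative of scaling, filter, fit and left-out array: CAR and PXR, Nrf2, male-biased, periportal, and coagulation and complement, with highest adjusted p of 0.0285, 6.01e-07, 1.99e-04, 0.0492 and 0.00278. The 16 probe sets became 28 without control replicate 1, 16 without control replicate 2, 11 and 12 without fraction 1 replicate a and b, and 3 without either fraction 2 array. Of the 11 genes, these omissions ended the calls of 2, 2, 4, 3, 9 and 9, and of the 17 lists 6, 5, 0, 0, 9 and 2. Cyp2c55 and Hsd3b5 passed in all 6 omissions.

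The comparison of fraction 1 with fraction 2 asked whether the fractions differed from each other. Only 2 probe sets passed, and neither has a single gene symbol, so no named gene passed. With camera at the preset correlation, male-biased, interferon-stimulated, and coagulation and complement genes were lower as groups after fraction 1 than after fraction 2, and targets of CAR and PXR, cholesterol synthesis genes and ribosomal protein genes were higher. With an estimated correlation none of these 6 lists passed (adjusted p = 0.586 for each).

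With limma, 2 of 14755 probe sets passed. Probe set 1423556_at, with no symbol, read 2277 and 2763 array units after fraction 1 and 484 and 540 after fraction 2, a difference of 2.26 (adjusted p = 0.0445). Probe set 1415896_x_at, with several symbols, read 276 and 266 against 1393 and 1167, a difference of -2.17 (adjusted p = 0.0445). Both are named because they were the 2 that passed, and so were chosen after their values were seen. At an unadjusted p under 0.05 there were 1187 probe sets, against 738 by chance, and 129 had a p under 0.01 with at least a 2-fold difference. Chance gives 148 at that p whatever the fold. The groups did not overlap in 6911 probe sets, or 46.8% where chance gives 33.3%. The fit with scan batch as a block called 0 by limma, with 1249 at an unadjusted p under 0.05. With chip lot as a block 16 passed, 9 higher and 7 lower, both of the 2 among them. In that fit Cyp39a1, Nnmt, Igfbp1, Fkbp5 and Alas1 were higher and Keg1, Slco1a1 and C9 lower (adjusted p from 0.0137 to 0.0375).

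Among genes taken by the smallest p, none of which passed in the main fit, the bile acid enzyme Cyp39a1 stood 2.17 higher after fraction 1, Igfbp1 3.27 and Nnmt 2.45. Reg3b, Sqle, Setd4, Fkbp5 and Ccn2 stood 1.11 to 1.74 higher, and adjusted p for these 8 ran from 0.17 to 0.224. Lower after fraction 1 stood Keg1 (-1.26, adjusted p = 0.121), Luzp1 (-2.10), Hsd3b5 (-2.46) and Slco1a1 (-2.94). The size for Hsd3b5 depends on the pseudocount, since its signal after fraction 1 lay below it. Cyp2d13, Cited2 and Hexim1 stood at -1.42 to -1.28, and Ctse at -1.31 with its other probe set at 1.10. Cyp2b10 stood 1.32 higher (adjusted p = 0.238), with 1.14 in the blocked fit. Of the genes fixed in advance, Cyp7a1, Cyp3a11, Cyp1a2, Cyp4a14, Abcb1a, Fasn and Saa1 stood at 0.69, 0.17, -0.47, -0.05, 0.10, -0.16 and -1.76, with adjusted p from 0.617 to 0.991. Cyp4a14 turned to 1.14 without fraction 1 replicate b and to 0.05 without fraction 2 replicate b, Abcb1a turned to -0.10 without fraction 2 replicate a, Fasn turned to 0.05 and 0.12 with scan batch and chip lot as a block, and a second probe set of Cyp7a1 stood at -0.18.

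No member of the lists passed over all genes in the main fit of this comparison. Adjusted over the list alone, 7 of 14 male-biased genes were lower, among them Hsd3b5, Slco1a1 and Serpina12 (-1.25). Their median was -0.79 (adjusted p = 4.26e-09 with camera; adjusted p = 0.586 with an estimated correlation), -0.83 in the blocked fit (adjusted p = 1.77e-07) and -0.79 within batch 1. Of 18 CAR and PXR targets, 3 were higher when adjusted over the list alone, and Alas1, the first enzyme of haem synthesis, stood at 1.20. Their median was 0.32 (adjusted p = 1.92e-06 with camera; adjusted p = 0.586 with an estimated correlation), 0.25 in the blocked fit (adjusted p = 1.33e-05) and 0.32 within batch 1. In cholesterol synthesis, 2 of 19 genes were higher when adjusted over the list alone, with Sqle at 1.19 and Hmgcs1 at 0.57. The median was 0.47 (adjusted p = 5.71e-04 with camera; adjusted p = 0.586 with an estimated correlation), 0.60 in the blocked fit (adjusted p = 1.77e-07) and 0.54 within batch 1. Without fraction 1 replicate b it was 0.26, and without fraction 2 replicate b 0.29.

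Of 20 interferon-stimulated genes, 3 were lower when adjusted over the list alone, and the chemokine gene Cxcl9 stood at -2.72 and Oas1a at -1.58. Their median was -0.23 (adjusted p = 4.56e-04 with camera; adjusted p = 0.586 with an estimated correlation), -0.34 in the blocked fit (adjusted p = 4.64e-05), -0.33 within batch 1, -0.36 without fraction 1 replicate a and -0.39 with chip lot as a block. Of 26 coagulation and complement genes, 5 were lower when adjusted over the list alone, and C9 stood at -1.35. Their median was -0.13 (adjusted p = 0.00104 with camera; adjusted p = 0.586 with an estimated correlation), -0.11 in the blocked fit (adjusted p = 6.48e-04) and -0.11 within batch 1. Without fraction 1 replicate a and b it was -0.21 and -0.08, and after quantile normalization and median centring -0.19 and -0.21. Of 46 ribosomal protein genes none passed, also when adjusted over the list alone, but 42 lay above 0, with Rpsa at 0.50. Their median was 0.23 (adjusted p = 4.26e-09 with camera; adjusted p = 0.586 with an estimated correlation), 0.18 in the blocked fit (adjusted p = 1.06e-06) and 0.21 within batch 1. After quantile normalization and median centring it was 0.11 and 0.15, and with chip lot as a block 0.15. The brightest 2% of probe sets, without the hepatocyte markers, had medians against control of -0.0475 after fraction 1 and -0.21 after fraction 2. How much of the ribosomal difference follows this general difference of bright probe sets was not tested. Nrf2 targets did not pass (median 0.19, adjusted p = 0.1), but did with scan batch as a block (median 0.26, adjusted p = 2.94e-04) and with chip lot as a block (median 0.28, adjusted p = 2.75e-04).

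Of 44 lists 12 passed with the preset correlation, 7 higher and 5 lower after fraction 1, and 0 with an estimated one. Of the 12, the 6 described as passing here are just those that held in every alternative of scaling, filter, fit and left-out array. Their highest adjusted p over these alternatives were 3.63e-05 (male-biased), 3.20e-04 (CAR and PXR), 0.0456 (cholesterol synthesis), 0.0239 (interferon), 0.0444 (coagulation and complement) and 2.39e-04 (ribosomal). The 2 probe sets became 11 others without fraction 1 replicate a and 0 without fraction 1 replicate b or either fraction 2 array, and of the 12 lists 2, 2, 3 and 1 were lost without fraction 1 replicate a, b and fraction 2 replicate a, b.

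The changes after the fractions were also set side by side over all 14755 probe sets. Of 54 probe sets higher after fraction 1, 53 had the same sign after fraction 2, and 13 passed in both. Of 51 lower after fraction 1, 49 had the same sign and 2 passed in both. With no change, the same number of probe sets picked on fraction 1 had the same sign in 49.7 of 54 and 46.7 of 51 simulated cases on average (SD 2.31 and 1.81), because the 2 controls are shared. Independent lists of these sizes would share 0.0512 and 0.00691, figures that leave out the shared controls. Genes that passed in both comparisons included Cyp2c55, Cyp2b10, Gstm2, Gstm3, Tubb2a and Slco1a4, which rose, and Hsd3b5 and Serpina12, which fell, the latter after fraction 2 only with all 6 arrays in the fit. The median change of probe sets higher after fraction 1 was 1.73 there and 1.09 after fraction 2, and of those lower -1.55 and -0.57. These sets were picked on fraction 1, which favours the larger size there, and the shared controls carry part of it into fraction 2. Across probe sets, which are not independent replicates, the fold changes had r = 0.548. Because both comparisons share the same 2 controls, unchanged groups whose probe sets varied independently, with no batch effect, gave r = 0.5 in 100 simulated draws (SD 0.00987, highest 0.521). The covariance was 0.0957, against 0.0483 simulated, a difference of 0.0474. The same sign was seen in 67.4% of probe sets, against 66.7% simulated and 67.8% at most. Simulated groups gave 0.05 probe sets called in both on average, against 15 observed, but they also gave only 0.52 called for fraction 1, against 105. Part of the excess may come from the shared controls. The simulated arrays of a probe set all had the same spread. The observed control arrays differed more (SD of their difference 0.603) than the arrays of fraction 1 (0.429) or fraction 2 (0.438). A wider spread of shared controls raises r and the covariance with no change. The excess of both over the simulated values, here and in the designs below, therefore cannot be told apart from that spread. The correlation was 0.728 and 0.686 without control replicate 1 and 2, where unchanged groups simulated in the same designs gave 0.666 and 0.667. It was 0.408 without fraction 2 replicate b, where they gave 0.408 too, and 0.702 in scan batch 1 alone, where they gave 0.577. With scan batch as a block it was 0.624 against 0.447 simulated, and with chip lot as a block 0.568 against 0.501. The covariance exceeded the simulated one by 0.123, 0.0575, 0.0363, 0.115, 0.0683 and 0.0413 in these 6 designs.

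**Figure D3:**
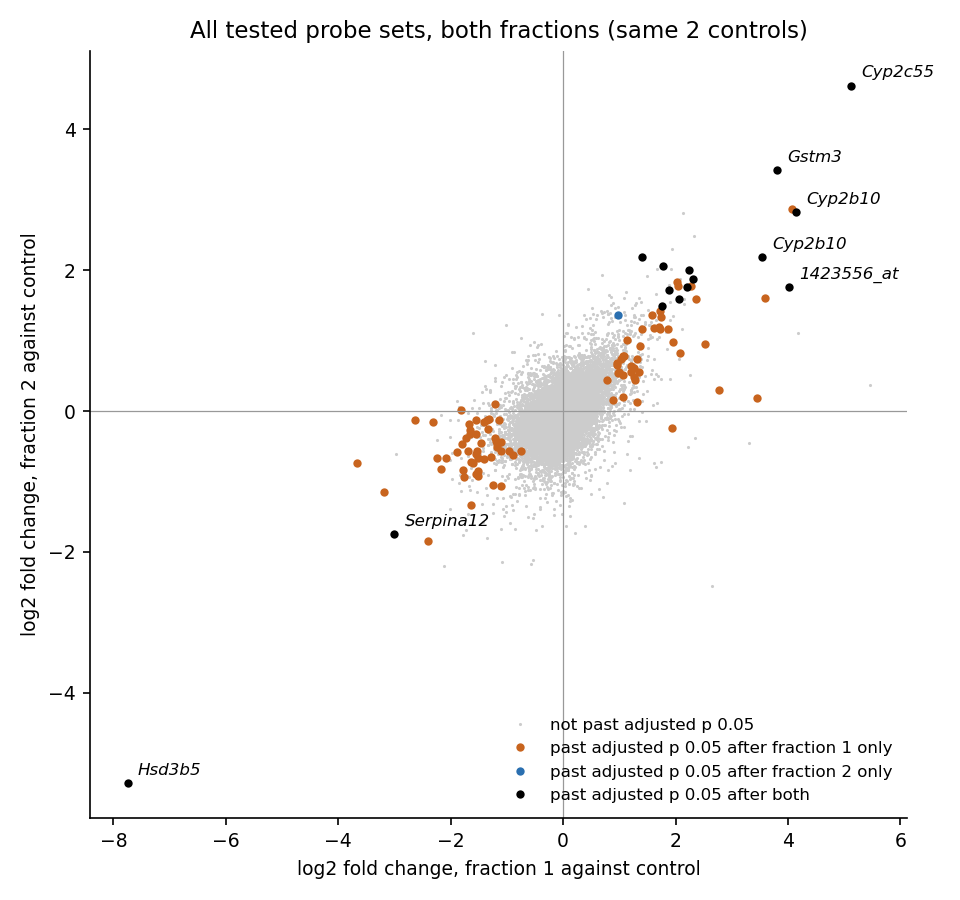
Log2 fold change of each tested probe set after fraction 1 (horizontal) and after fraction 2 (vertical), against the same 2 controls, coloured by which comparison it passed at an adjusted p of 0.05. The 15 probe sets that passed in both include Cyp2c55 at 5.12 and 4.62 and Hsd3b5 at -7.75 and -5.28.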

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

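The fits to scan batch 1 alone and with chip lot as a block were chosen after the data were seen. The other alternatives given here were planned. Scan batch 1 alone holds a single control and a single fraction 2 array, so its spread comes from the fraction 1 arrays only. Every named gene past the threshold kept its direction in all 19 alternatives of its comparison, apart from Gadd45b, whose dimmer probe set stood at -0.144. Only quantile normalization, median centring, chip lot as a block and, after fraction 1, scan batch as a block could have turned a direction. In the other alternatives the fold change stayed the same, or could not turn because the groups of these genes did not overlap. The counts were less stable. In the group tests, no list's call held with an estimated correlation or with fry: 0 lists in each of the 3 comparisons with either. Of the 45 results of named genes that passed, all 45 lost their call in the plain test, 37 with no variance trend, 28 with no filter, 27 in scan batch 1 only, 20 in a fit of the 2 groups compared and 9 with chip lot as a block. Of the 45 list results that passed, 18 lost it with their direction kept in scan batch 1 only, 11 after quantile normalization, 10 with no variance trend and 5 with scan batch or with chip lot as a block. Low signal limits the size of a change: after fraction 1, Hsd3b5 read 8.25 array units, under the pseudocount. Except where the construction shows it (fewer arrays, fewer or more probe sets tested), the cause was not tested.

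For fraction 1 against control (105 probe sets), 48 passed with arrays centred on their median, 27 with no filter, 12 with no variance trend, 39 in a fit of the 2 groups compared, 66 in scan batch 1 only and 0 in a plain test per probe set without moderation, which had 1190 at an unadjusted p under 0.05. Leaving out 1 array gave 14 to 149. For fraction 2 against control (16), 10 passed with no filter, 2 with no variance trend, 9 in a fit of the 2 groups compared, 4 in scan batch 1 only, 10 with chip lot as a block and 0 in the plain test, with 798 at an unadjusted p under 0.05. Leaving out 1 array gave 3 to 28. Median centring moved the median of all probe sets in this comparison from -0.0414 to 0.0737. The lists (17) became 9 after quantile normalization, 9 in scan batch 1 only, and 9 to 17 when 1 array was left out. Between the fractions (2), limma called 0 with quantile normalization, median centring, a pseudocount of 1, no filter, no variance trend, scan batch as a block or scan batch 1 only, where 1150, 1154, 1179, 1615, 1087, 1249 and 1329 had an unadjusted p under 0.05. The plain test also called 0, with 1278, and 16 passed with chip lot as a block. Leaving out 1 array gave 0 to 11.

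The correlation of the fold changes (0.548) was 0.702 in scan batch 1 only and 0.408 to 0.728 when 1 array was left out. Unchanged groups simulated in these designs, with the same spread in every array, gave 0.577 and 0.408 to 0.667. Where they gave 0.408, without 1 array of either fraction, the observed values were 0.408 to 0.545.

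With the replicate letters a and b as a block between the fractions, 75 probe sets passed, 34 higher and 41 lower, among them both of the 2, and of 31 results of named genes 18 gained a call. The a minus b differences of the fractions had r = 0.0301 across probe sets, so the letters did not pair the arrays by this measure.

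Genes that changed sign and lists whose test changed direction were these, none of them past the threshold except Gadd45b and the ribosomal, cholesterol and pancreas lists after fraction 2. After quantile normalization, ribosomal proteins (fraction 2) had a median of 0.00123, Fasn (fraction 1) stood at -0.0197, Cyp3a11 and Cyp1a2 (fraction 2) at 0.233 and 0.0399, and Cyp4a14 between the fractions at 0.018. With median centring Cyp3a11 and Cyp1a2 (fraction 2) stood at 0.103 and 0.11. The AhR targets (fraction 1, median -0.0882, mean 0.0205) turned by their test with no filter (-0.0923), a filter at the 60th percentile (-0.178) and in scan batch 1 only (-0.203). There too Cyp3a11 (fraction 1) stood at -0.0532, Cyp1a2 (fraction 2) at 0.0598 and Abcb1a between the fractions at -0.0998. With chip lot as a block, the pancreas markers (fraction 2) had a median of -0.13, Cyp3a11 and Cyp1a2 (fraction 2) stood at 0.0995 and 0.056, and Fasn between the fractions at 0.118. With scan batch as a block, Cyp4a14, Abcb1a and Fasn between the fractions stood at 0.243, -0.00858 and 0.0529. Other probe sets between the fractions stood at 1.1 for Ctse, -0.184 for Cyp7a1 and -0.205 for Abcb1a. Of lists that passed after fraction 2, some lost the call and changed the sign of the median but not the direction of the test: heat shock proteins (-0.26) to 0.0027 in scan batch 1 only, proteasome subunits (0.075) to -0.0143 without fraction 2 replicate a, and ribosomal proteins (-0.11) to 0.00553 with median centring.

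When 1 array was left out, after fraction 1 the AhR targets ranged from -0.203 to 0.0934, Eif2s3y from -0.452 to 0.599, Cyp3a11 from -0.0532 to 0.37, Cyp4a14 from -2.33 to 0.0467, Fasn from -0.439 to 0.512 and Saa1 from -1.5 to 0.734. After fraction 2, cholesterol synthesis (median 0.15) ranged from -0.121 to 0.319, Cyp7a1 from -0.301 to 1.05, Cyp3a11 from -0.224 to 0.199, Cyp1a2 from -0.296 to 0.285 and Fasn from -0.282 to 0.668. Between the fractions, Cyp4a14 ranged from -1.24 to 1.14 and Abcb1a from -0.0998 to 0.301.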

Other observations

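The tests that weigh explanations in this part were chosen after the results were seen, as was the fit with chip lot as a block. After fraction 1, further groups were lower with the preset correlation, and each lost its call when certain arrays were left out. Of 18 heat shock protein genes, Hsph1 fell by 1.77, a call lost with scan batch as a block (adjusted p = 0.0726) and whichever array was left out, and 17 did not pass, with Hspa1a at -1.98 (adjusted p = 0.149); adjusted over the list alone, 4 fell. The list's median was -0.39 (adjusted p = 6.19e-04; adjusted p = 0.509 with an estimated correlation), and -0.22 without control replicate 1 (adjusted p = 0.173, with 1.11e-05 to 0.207 over the alternatives). The 16 clock genes had a median of -0.45 (camera, adjusted p = 0.0162, or 0.4 with an estimated correlation). With scan batch as a block that median was -0.34 (adjusted p = 0.121). After fraction 2 it was -0.32 (adjusted p = 0.0475, or 0.52 with an estimated correlation). Leukotriene and prostaglandin genes and periportal genes had medians of -0.21 and -0.25 after fraction 1 (adjusted p = 0.0451 for each). Scan batch as a block ended both calls. Of 10 MHC class I and II genes none passed and, adjusted over the list alone, 1 fell. Their median was -0.28 (adjusted p = 0.00483; adjusted p = 0.509 with an estimated correlation), and -0.15 without control replicate 2 (adjusted p = 0.0909, with 0.00207 to 0.0909 over the alternatives).

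Among cell type markers after fraction 1, 12 endothelial and 14 stellate cell and fibroblast markers had medians of -0.32 and -0.43 (adjusted p = 0.0272 and 0.0329; adjusted p = 0.4 and 0.6 with an estimated correlation). None passed singly, and adjusted over each list alone 1 fell in each. Without control replicate 2 the medians were -0.20 and -0.24 (adjusted p = 0.0909 and 0.209), and without fraction 1 replicate b -0.28 and -0.25 (adjusted p = 0.0521 and 0.0756). Without control replicate 1 the endothelial median was -0.34 (adjusted p = 0.0534), and with chip lot as a block the stellate median was -0.28 (adjusted p = 0.0458). Over the alternatives, adjusted p ran from 0.0229 to 0.0909 for the endothelial and from 0.0225 to 0.209 for the stellate list. In oxidative phosphorylation, 64 of 77 genes were above 0 in fraction 1 against fraction 2, with a median of 0.15 (adjusted p = 4.03e-04; adjusted p = 0.586 with an estimated correlation), and none passed singly, also when adjusted over the list alone. That median was 0.07 with scan batch as a block (adjusted p = 0.0121), 0.08 with chip lot as a block and 0.07 with median centring. After quantile normalization it was 0.07 (adjusted p = 0.163, with 7.78e-05 to 0.163 over the alternatives). How much of it follows a general difference of bright probe sets between the fractions was not tested.

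The lower male-biased liver genes after fraction 1 (median -1.54) were weighed against 3 technical explanations. Female animals in the fraction 1 arrays would leave the Y-linked Eif2s3y at least 1 log2 unit lower, but it stood at 0.0734 (95% interval -0.705 to 0.852), and at -0.452 without control replicate 2, which argues against them, although Xist, expressed from the inactive X of females, stood at 0.468 (adjusted p = 0.677; 0.0369 with scan batch as a block). A scan batch effect as the whole cause is argued against by the blocked median of -1.47 (adjusted p = 2.32e-12). A lower share of hepatocyte RNA would lower the hepatocyte markers by about as much, and their median was -0.266 (SD 0.111 over the 8 markers). What stays open, as an untested hypothesis, is that the diet, or a difference between animals such as their state when sampled, may have lowered these genes.

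Transcripts of exocrine pancreas differed between arrays: the mean log2 of 10 markers ran from 10.59 in fraction 1 replicate a to 12.28 in fraction 1 replicate b, with Ctrb1 at 4138 and 11575 and Cela1 at 2676 and 5213 array units. After fraction 2 their median was 0.47 (adjusted p = 0.0437; adjusted p = 0.752 with an estimated correlation), but -0.13 with chip lot as a block (adjusted p = 0.807), 0.11 without control replicate 2 (adjusted p = 0.788) and 0.07 without fraction 2 replicate a (adjusted p = 0.997, with 3.20e-04 to 0.997 over the alternatives). Diet as the whole cause is argued against by a difference of 1.69 between 2 arrays of 1 group, where group means differed by at most 0.433. Pancreatic tissue taken along with the liver stays open. The markers moved together, with an inter-gene correlation of 0.972 against 0.641 for the hepatocyte markers, but not in 1 ratio. From fraction 1 replicate a to b, Cela1 rose by 0.958 and the others by 1.48 (Ctrb1) to 2.11 (Prss2). The departure from 1 ratio thus rests mainly on Cela1. No other list holds any of the 10, and how much of them liver itself expresses was not measured.

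Hepatocyte markers were lower after both fractions, with medians of -0.266 and -0.395. The p-values of this paragraph are from camera at the preset correlation. With an estimated correlation the list passed after neither fraction (camera, adjusted p = 0.6 and 0.52). After quantile normalization they were -0.0717 (adjusted p = 0.323) and -0.0283 (adjusted p = 0.953), but all 8 lie in the brightest 2% of probe sets, where that method makes arrays alike, so scaling of bright probe sets and a real decrease cannot be told apart. The other 287 probe sets of the brightest 2% had medians of -0.0475 and -0.21, and the other 67 of the brightest 0.5%, which holds 7 of the 8, -0.12 and -0.286. Without control replicate 2, whose RNA had the highest 3'/5' ratios, the medians were -0.128 and -0.29. That fit leaves a single control array. Its test at the preset correlation treats the markers as nearly independent, while their estimated correlation was 0.64. It therefore cannot decide whether that array was the whole cause after either fraction. An effect of the diet stays open and untested.

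Skeletal muscle markers, 8 genes, had their highest mean log2 of 9.26 in control replicate 2 and 7.55 to 8.64 in the other 5 arrays.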
